A study of Mus musculus and Rattus norvegicus with 6 samples.

How the data were processed

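Per the labels' protocols, retinas were dissected from eyes kept in RNAlater, total RNA with miRNA was isolated with a miRNeasy mini kit, and Illumina small RNA libraries were read as 50-base single-end reads on a HiSeq-2500. The protocol text names rat eyes for the samples of both species. The labels give 3 mouse (C57BL/6) and 3 rat (Sprague Dawley) samples of 9 weeks, all wild type, and speak of biological samples in triplicate, without saying that each came from a separate animal. The p-values therefore measure the spread between these libraries, which may be technical in part. Each species was counted and tabulated on its own. Whether the libraries of both species were made and sequenced together is not known here. A difference in annotation, library batch or read processing between the tables therefore cannot be told apart from the species. Strain changes with the species as well, so a strain difference cannot be told apart from a species difference.

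The authors deposited raw counts per mature miRNA name, whole numbers with no normalization, in 1 table per species. Trimming, aligner, mismatches, the miRNA annotation release and the treatment of reads that match several names are not given in the sources used here. Reads that match several names may be counted more than once or divided between the names. In mouse library m1, miR-486a-5p and miR-486b-5p had 2555 and 2665 counts. In rat library r1, miR-129-1-3p and miR-129-2-3p had 19852 counts each. Members of families with near-identical sequences (let-7, miR-181, miR-30, miR-17-92, miR-129, miR-1, miR-344b, miR-466, miR-486) are uncertain for this reason. Names were matched and not sequences, so a name in both tables can stand for sequences that differ in length or base. The floor of 3 counts covers counting error only, and takes reads as independent although PCR copies are not. The columns are named m1, m3, m4, r1, r2 and r4, while the labels number the samples 1 to 3, so each column was assigned to its species and not to a numbered sample. Depth was 24169628 to 30514632 counts per library, at which 10 counts correspond to less than 1 CPM.

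Names were joined after the species prefix was removed. Exact names gave 542 shared miRNAs, with 1373 names in the mouse table only and 222 in the rat table only, and no name was repeated within a table (0 repeats). A relaxed match added 44 pairs that differ by a letter or a missing arm suffix (586 names). A wider match, chosen after the data were examined, added another 23 names without an arm suffix, joined to the arm with at least 10 times the counts of its partner (609 names).

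Abundance was tested with edgeR 4.0.16 in R 4.3.3: filterByExpr (398 miRNAs kept), TMM factors on the totals of the shared names, and the quasi-likelihood F test over all 6 libraries with species as the only term. A miRNA was called at a Benjamini-Hochberg adjusted p under 0.05. Lists were tested with camera (limma 3.58.1) on log2 CPM with a preset correlation of 0.01, the more abundant arm standing for each miRNA, and lists with under 3 tested members were given values only. There were 18 lists: the cluster of miR-183, miR-96 and miR-182, light-regulated retinal, neuronal and glia-enriched miRNAs, the let-7, miR-181, miR-29, miR-30, miR-15/16 and miR-17-92 families, the Dlk1-Dio3 locus, the rodent cluster of miR-297, miR-466, miR-467 and miR-669, and miRNAs of vascular and mesenchymal, red blood, leukocyte and microglia, cornea and lens, epithelial and muscle cells. The lists share members: miR-204 is among light-regulated and glia-enriched miRNAs, miR-29a among glia-enriched and miR-29, and miR-183, miR-96 and miR-182 among the first 2. Arm usage was tested with limma on log2((5p + 0.5)/(3p + 0.5)) for hairpins with both arms in both tables (232) and a sum of at least 50 counts in every library (169). Detection, concentration and profile correlation are values with no test. Hairpin GC content and the position of miRNA genes relative to each other were taken from the mouse annotation of GRCm38.p6, used only for these.

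The rule for named miRNAs, fixed with the lists and tests before the data were examined, took the 15 most abundant names per species. It also took the 10 largest rises and 10 largest falls among called miRNAs with at least 100 CPM in a species and no overlap between the species' libraries, and up to 4 of the most abundant members of each list. The last were the 5 largest arm changes each way with every called change of the dominant arm, and the 5 most abundant names listed in 1 table only. A miRNA named outside this rule was chosen after its values were seen. In the abundance and arm paragraphs these are miR-129-2-3p, miR-181b-2-3p, miR-185-3p, miR-208a-3p and miR-344b (as abundance). Among list members they are miR-132-3p, miR-212-5p, miR-30b-5p and miR-208a-3p.

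The tests were run on simulated counts with the means, dispersion and totals of these libraries. For abundance (398 miRNAs, 200 changed, 10 runs), 84.3% of 2-fold and 98.8% of 4-fold changes were recovered, and 2.29% of calls were false. For arm usage (169 hairpins, 10 runs), 72.3% of 4-fold changes in ratio were recovered and 5.82% of calls were false. For the list test, a shifted list was called in 10 of 10 runs and an unshifted list in 0 of 10. This holds for the simulated shift only, whose size is not stated here. It does not give the power of the test for the list medians reported below.

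The alternatives tried were DESeq2 1.42.0, library totals alone, RLE and upper quartile factors, totals of all names, leaving out the 10 most abundant miRNAs, other filters on low counts, relaxed and wider names, a test against a fold of 2, limma-voom with and without sample weights, fry, an estimated correlation, both arms, other pseudocounts and minimum sums, thinning to the shallowest library, and leaving out each library in turn. Tables and figures were made with Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.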

Results

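Small RNA was sequenced from the retinas of wild-type C57BL/6 mice and Sprague Dawley rats, both 9 weeks old, with 3 libraries per species. The retina is the light-sensing neural layer of the eye. MicroRNAs (miRNAs) are short RNAs cut from either side of a hairpin, the 5p and the 3p arm, that lower the output of target messenger RNAs. The question set by the labels was which miRNAs the retina of each species holds and how the species compare. The mouse libraries held 27843590 (m1), 30514632 (m3) and 28183496 (m4) counts on 1915 mature names. The rat libraries held 24169628 (r1), 25296431 (r2) and 28198305 (r4) counts on 764 names. In total 542 names were the same in both tables apart from the species prefix, and only these entered the tests between species. They held 72.5% ± 1.01 (SD, n = 3) of the counts in mouse and 66.8% ± 2.80 (SD, n = 3) in rat.

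Both retinas were dominated by the cluster of miR-183, miR-96 and miR-182, miRNAs made from 1 transcript in photoreceptors and other sensory cells. The cluster held 44.7% ± 1.53 (SD, n = 3) of all mouse counts and 41.1% ± 6.81 (SD, n = 3) of all rat counts. In mouse, miR-183-5p led with 24.2% ± 0.699 (SD, n = 3) and miR-182-5p followed with 19.4% ± 1.04 (SD, n = 3). In rat the order was the other way round: the name miR-182 held 23.7% ± 4.81 (SD, n = 3) and miR-183-5p held 16.1% ± 2.27 (SD, n = 3). The let-7 family with miR-98 came next, with 15.7% ± 0.740 of counts in mouse and 13.7% ± 0.974 in rat (SD, n = 3 each). The neural miRNA miR-9 (both arms; listed as miR-9 in mouse and miR-9a in rat) held 5.83% ± 0.0869 in mouse and 6.78% ± 1.93 in rat (SD, n = 3 each). The miR-30 family held 7.29% ± 0.310 in mouse and 6.01% ± 1.59 in rat (SD, n = 3 each). The pair miR-204 and miR-211, abundant in the retinal pigment epithelium and also made in the neural retina, held 1.51% ± 0.119 in mouse and 2.75% ± 0.326 in rat (SD, n = 3 each).

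Of the 15 most abundant names per species, 11 were the same by exact name and 13 once renamed pairs were joined. Those in mouse were, in falling order, miR-183-5p, miR-182-5p, let-7f-5p, miR-9-5p, let-7g-5p, miR-30d-5p, miR-26a-5p, miR-30a-5p, miR-181a-5p, miR-99a-5p, miR-7a-5p, miR-124-3p, miR-148a-3p, let-7i-5p and let-7a-5p. Their shares ran from 24.2% down to 1.25%. In rat, miR-129-5p at 1.83% ± 0.421 and miR-204-5p at 1.65% ± 0.203 (SD, n = 3 each) stood among the 15, and miR-124-3p and let-7a-5p did not. The 10 most abundant names held 73.1% ± 0.698 (SD, n = 3) of mouse counts and 67.8% ± 4.50 (SD, n = 3) of rat counts. Counts were so concentrated that 3 miRNAs in mouse and 4 in rat made up 50% of the mean profile, and 28 and 31 made up 90%. At least 10 counts in each of the 3 libraries were found for 625 of the 1915 mouse names and 452 of the 764 rat names. Among the 542 shared names, the numbers were 380 in mouse and 368 in rat. With at least 1 count in each library, the mouse number was 944.

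**Figure D1:**
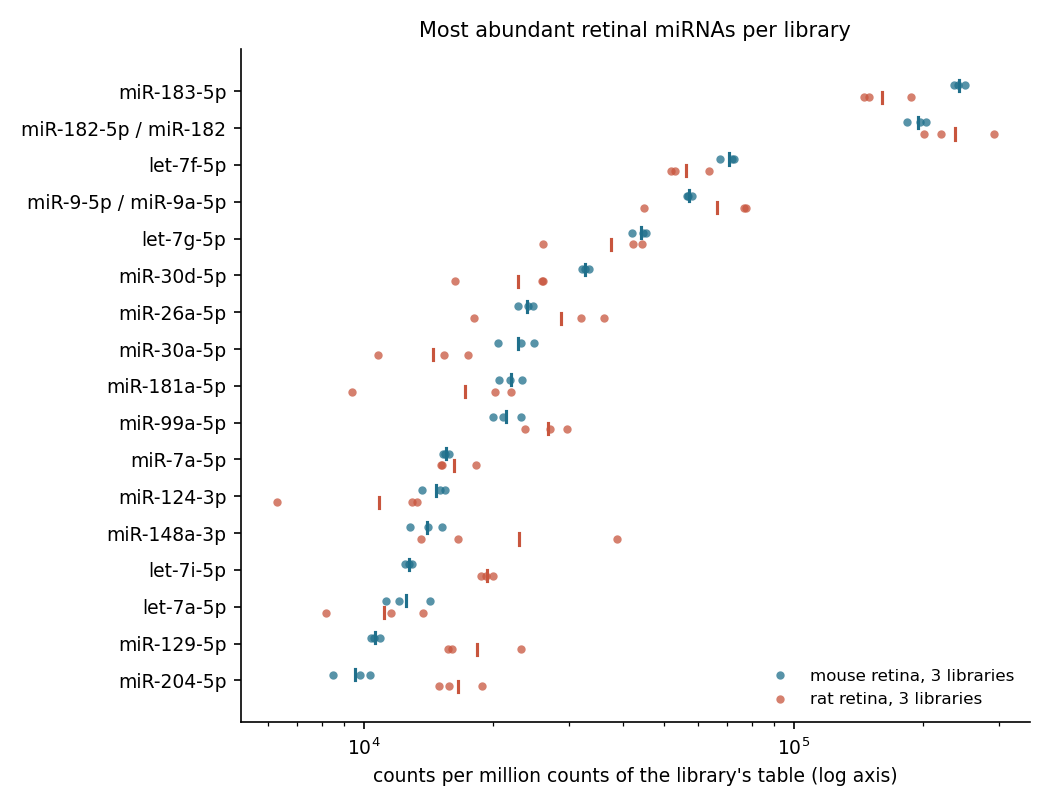
Level of the most abundant miRNAs of either species, as CPM of all counts in the library's table on a log axis; each point is 1 library (3 mouse, 3 rat) and each tick the mean. Double names give the mouse and the rat name; miR-183-5p lay between 235760 and 249606 in mouse and between 145781 and 186770 in rat.

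The mean profiles of the species were close across the 542 shared names, with Pearson r = 0.962 and Spearman rho = 0.947 on log2(CPM + 1), where CPM is the count scaled to a common library total. These are correlations across miRNAs, which are not independent replicates, so no p is given. Between libraries of 1 species the Pearson r was 0.999 for each mouse pair and for rat libraries r2 and r4. Rat library r1 stood apart, with r = 0.989 against r2 and 0.990 against r4. In r1, miR-148a-3p reached 38754 CPM of all counts, against 13607 in r2 and 16578 in r4, while miR-181a-5p reached 9413 CPM, against 21998 and 20174. No pair of libraries looked like 1 library read again: the lowest chi-square per degree of freedom of a pair within a species was 105, which takes reads as independent and shows nothing beyond this.

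Many miRNAs differed between the retinas of the species. Of 398 tested, 102 were higher and 97 lower in rat at an adjusted p under 0.05 (called below), 50% of those tested. Among the called, 68 were over 2-fold higher and 51 over 2-fold lower in rat, and 15 and 5 passed 16-fold. Of the miRNAs in this test named below with at least 100 CPM in a species, only miR-181a-2-3p, miR-363-3p and miR-381-3p passed 16-fold. Some others lay near the floor, such as miR-208a-3p at 0 CPM in mouse and 0.683 in rat. All 3 libraries of 1 species lay above all 3 of the other for 238 of the 398 miRNAs (59.8%), where chance gives 10%. The median size of the difference was 0.63 on the log2 scale, and 85 of the 158 miRNAs with at least 100 CPM in a species were called. Levels in this and the next paragraphs are CPM of the shared names after scaling, with the edgeR quasi-likelihood test and Benjamini-Hochberg adjusted p. Scaled by library totals alone, 170 were called, of which 74.7% were higher and 43 miRNAs lower, against 51.3% higher in the main test, and the median of all tested miRNAs moved up by 0.36 (log2). Without rat library r1, 293 were called, including every miRNA called with it.

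The largest rise among miRNAs of at least 100 CPM was in miR-181a-2-3p, the minor-arm product of a hairpin that also gives miR-181a-5p. It had 10 counts in all 3 mouse libraries together and 259 CPM ± 58.6 (SD, n = 3) in rat, a log2 difference of 10.46 ± 0.37 (SE; adjusted p = 1.18e-07). The same hairpin cluster's miR-181b-2-3p differed by 0.29 ± 0.33 (adjusted p = 0.498). The miRNA miR-363-3p, of the X-linked paralog of the miR-17-92 cluster, rose from 1.06 CPM ± 0.113 in mouse to 207 CPM ± 94.7 in rat (SD, n = 3 each), a log2 difference of 7.59 ± 0.46 (adjusted p = 1.79e-06). In rat library r1 its count was 1243, against 6380 and 5983 in the others. The neuronal miR-129-1-3p reached at most 160 CPM in the mouse libraries and at least 1388 CPM in the rat libraries (log2 difference 3.36 ± 0.17, adjusted p = 5.91e-07). In rat miR-129-1-3p and miR-129-2-3p had the same count in each library, so 1 set of reads stands under both names there, and part or all of this rise can come from counting; miR-129-2-3p rose by 0.84 ± 0.16 (adjusted p = 0.00213). The miRNAs miR-493-5p (2.77 ± 0.23), miR-323-3p (2.51 ± 0.15) and miR-329-3p (2.14 ± 0.14), all encoded in the imprinted Dlk1-Dio3 locus, also rose, with adjusted p of 1.32e-05, 1.80e-06 and 2.97e-06. So did miR-3068-3p (2.81 ± 0.17, adjusted p = 1.80e-06) and miR-325-5p (2.34 ± 0.15, adjusted p = 2.65e-06). For miR-148a-5p (2.77 ± 0.40) and miR-378b (2.63 ± 0.41) the size leaned on r1: without it the log2 differences were 2.14 and 1.91, with both still called.

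The largest fall among miRNAs of at least 100 CPM was in miR-381-3p, also of the Dlk1-Dio3 locus. It lay between 3046 and 3814 CPM in the mouse libraries and was at 9.74 CPM ± 0.716 (SD, n = 3) in rat, a log2 difference of -8.51 ± 0.22 (adjusted p = 1.34e-08). For this name as for miR-181a-2-3p, the sequences behind the name in each table were not compared. The next were miR-130b-5p (-3.57 ± 0.22, adjusted p = 1.95e-06), miR-501-3p (-3.24 ± 0.17, adjusted p = 5.95e-07) and miR-484 (-3.18 ± 0.18, adjusted p = 1.16e-06). The abundance of miR-484 was 408 CPM ± 13.4 in mouse and 45.0 CPM ± 8.04 in rat (SD, n = 3 each). Falls of 2 to 4 fold were seen for miR-370-3p (-1.82 ± 0.20), miR-190b-5p (-1.55 ± 0.19), miR-183-3p (-1.36 ± 0.14), miR-199a-3p (-1.18 ± 0.20), miR-92b-3p (-1.12 ± 0.14) and the neuronal miR-128-3p (-1.09 ± 0.18). Their adjusted p lay between 5.39e-05 and 0.00112. The fall of miR-199a-3p was not called with library totals alone, where the log2 difference was -0.78. Against a fold of at least 2, 70 of the 398 miRNAs were called, 40 higher and 30 lower; miR-199a-3p, miR-92b-3p and miR-128-3p were not among them.

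**Figure D2:**
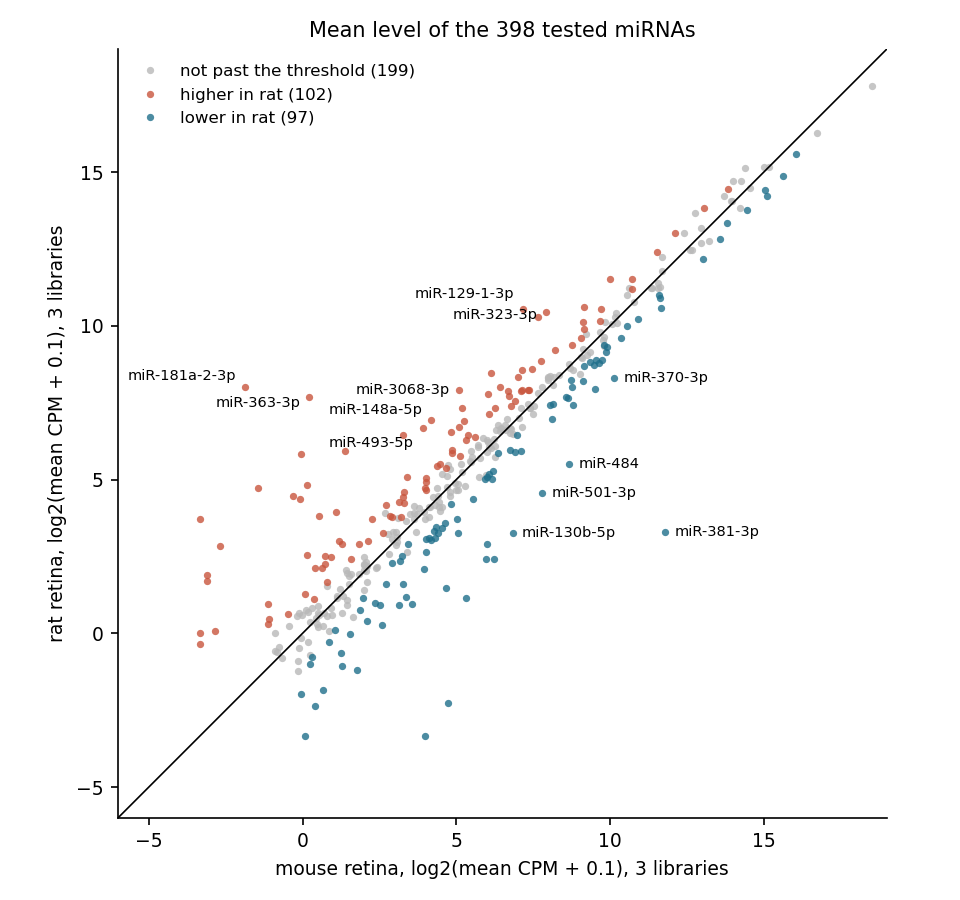
Mean level of each of the 398 tested miRNAs in mouse (x axis) and rat (y axis), as log2 of mean CPM of the shared names plus 0.1, over 3 libraries per species; the line marks equal levels. Red points were called higher in rat (102), blue points lower (97), and grey points were not called; miR-381-3p lies farthest below the line among the labelled miRNAs.

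Among the 14 lists of miRNAs with at least 3 tested members, none was called by camera with a preset correlation of 0.01, and 1 had an unadjusted p under 0.05. That list was the miR-181 family (p = 0.0406, adjusted p = 0.301; adjusted p = 0.889 with an estimated correlation). The rotation test fry, which asks whether a list moves on balance one way without comparing it with other miRNAs, called 4 lists. They were neuronal miRNAs (adjusted p = 0.0122), the miR-181 family (0.0214), muscle miRNAs (0.0214) and the let-7 family (0.0233). Their list medians were -0.50, -0.71, 0.53 and -0.47 in this order. Muscle members went both ways, from -1.11 (miR-133a-3p) to 6.74 (miR-208a-3p, at 0 CPM in mouse and 0.683 in rat). With wider names the muscle median was -0.80. The estimated correlation gave no called list, with adjusted p of at least 0.889.

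Of 10 tested neuronal miRNAs, 5 were lower in rat, 0 higher and 5 not called, and the list as a whole was not called (camera adjusted p = 0.301); adjusted over the list alone 5 fell. When 1 library was left out, between 4 and 6 fell, with 1 higher without r1. The brain and retina miRNA miR-124-3p fell from 22616 CPM ± 1503 to 13870 CPM ± 1425 (SD, n = 3 each), a log2 difference of -0.71 ± 0.17 (adjusted p = 0.00711). The activity-regulated pair miR-132-3p (-0.54 ± 0.20, adjusted p = 0.0494) and miR-212-5p (-0.96 ± 0.15, adjusted p = 0.000898), made from 1 transcript, also fell. The call of miR-132-3p was lost without m1, m3, m4, r2 or r4 and with DESeq2. The differences of miR-7a-5p (-0.05 ± 0.29) and miR-129-5p (0.72 ± 0.35) were not called. Library totals alone left 3 members lower and 1 higher, and ended the call of miR-124-3p. Rat library r1 held more miR-129-5p than r2 and r4, and without r1 the log2 difference of miR-129-5p was 0.12.

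All 4 members of the miR-181 family fell. These were miR-181a-5p (-0.63 ± 0.18, adjusted p = 0.0162), miR-181b-5p (-0.77 ± 0.18, 0.00709), miR-181c-5p (-0.91 ± 0.18, 0.00288) and miR-181d-5p (-0.42 ± 0.14, 0.0329), and adjusted over the list alone 4 fell. The let-7 family had 5 of 9 members lower, 0 higher and 4 not called (camera adjusted p = 0.301), and adjusted over the list alone 5 fell. The member let-7g-5p was at 67682 CPM ± 2682 in mouse and 49237 CPM ± 1812 in rat (SD, n = 3 each; log2 difference -0.46 ± 0.16, adjusted p = 0.0426). The differences of let-7f-5p (-0.43 ± 0.30), let-7a-5p (-0.38 ± 0.17) and let-7i-5p (0.47 ± 0.25) were not called. Of 4 members of the miR-15/16 family, miR-16-5p (-0.78 ± 0.24), miR-15b-5p (-0.92 ± 0.22) and miR-322-3p (-1.20 ± 0.24) fell and miR-15a-5p (-0.02 ± 0.35) was not called (camera adjusted p = 0.301). Adjusted over the list alone 3 fell. Here miR-322 entered by its 3p arm and the others by their 5p arms. With library totals alone, 0 members of these 3 families were called lower and 1 let-7 member was called higher, although each list's median stayed below 0, at -0.40 (miR-181), -0.16 (let-7) and -0.57 (miR-15/16). Without r1, 4, 7 and 3 members of the miR-181, let-7 and miR-15/16 families were called lower, but fewer were when any 1 mouse library was left out: 2 of the miR-181 family, 1 or 2 of the let-7 family and 2 of the miR-15/16 family, with miR-181a-5p, miR-181d-5p, let-7g-5p and miR-16-5p among those lost. Without r2 the let-7 number was 3, and without r4 it was 1, with 3 for the miR-181 family.

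Light-regulated retinal miRNAs split. Of 4 tested members, miR-204-5p (0.63 ± 0.21, adjusted p = 0.0345) and miR-211-5p (0.80 ± 0.20, adjusted p = 0.00866) rose. The 2 tested members of the cluster of miR-183, miR-96 and miR-182 were not called: miR-183-5p differed by -0.69 ± 0.32 (adjusted p = 0.107) and miR-96-5p by 0.13 ± 0.17 (adjusted p = 0.576). The list as a whole was not called (adjusted p = 0.746), and adjusted over the list alone 2 rose. In r1 the share of this cluster was 48.8%, against 36.1% and 38.3% in r2 and r4. Without r1 the log2 difference of miR-183-5p was -1.17 and was called, and that of miR-204-5p was 0.40. The call of miR-204-5p was lost when any 1 mouse library was left out. Of 6 glia-enriched miRNAs, miR-204-5p alone was called; miR-99a-5p (0.15 ± 0.21), miR-125b-5p (-0.48 ± 0.23) and miR-99b-5p (0.59 ± 0.27) were not (list adjusted p = 0.906; adjusted over the list alone 0). With library totals alone, 4 of these 6 were called higher, and without r1, 2 were called higher and 2 lower.

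The miR-30 family moved both ways: miR-30d-5p (-0.75 ± 0.17, adjusted p = 0.00535) and miR-30a-5p (-0.88 ± 0.19, adjusted p = 0.00417) fell, miR-30e-3p (0.89 ± 0.30, adjusted p = 0.0347; 0.42 without r1) rose, and miR-30c-5p (0.11 ± 0.20) and miR-30b-5p (0.01 ± 0.21) were not called (list adjusted p = 0.746). Adjusted over the list alone, 2 fell and 1 rose. The fall of miR-30d-5p was not called with library totals alone, nor the rise of miR-30e-3p when any 1 mouse library was left out. In the miR-29 list, miR-29c-5p rose (1.07 ± 0.26, adjusted p = 0.00783), and miR-29a-3p (-0.34 ± 0.20) and miR-29b-3p (-0.06 ± 0.19) were not called. Here miR-29c entered by its 5p arm and the others by their 3p arms. The miR-29 list was not called (adjusted p = 0.906; its median of -0.07 and mean of 0.19 differ in sign, and camera gave the direction up), and adjusted over the list alone 1 rose.

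The miR-17-92 cluster and its paralogs, which promote cell growth, also moved both ways, with 5 of 11 members higher, 4 lower and 2 not called. Beside miR-363-3p, miR-25-3p rose (0.47 ± 0.17, adjusted p = 0.0431), and miR-92a-3p (-0.83 ± 0.14, adjusted p = 0.00105) and miR-92b-3p (-1.12 ± 0.14, adjusted p = 0.000226) fell. The list was not called (adjusted p = 0.746); adjusted over the list alone, 5 rose and 4 fell. With library totals alone 5 rose and 1 fell, with miR-92a-3p not called, and when 1 library was left out 2 (without m4) to 6 (without r1) rose and 3 or 4 fell, with miR-25-3p not called when any 1 of the mouse libraries was left out. Of 36 members from the Dlk1-Dio3 locus, 14 rose, 5 fell and 17 were not called (list adjusted p = 0.328), and adjusted over the list alone 14 rose and 6 fell. Without r1, 20 rose and 9 fell; without any other 1 library, 11 to 13 rose and 5 or 6 fell. Here miR-379-5p rose from 1016 CPM ± 52.7 to 2943 CPM ± 1576 (SD, n = 3 each), a log2 difference of 1.53 ± 0.32 (adjusted p = 0.00410; 1.001 without r1). The most abundant member, miR-127-3p (0.52 ± 0.30), and miR-434-3p (0.30 ± 0.21) were not called. Of the rodent cluster of miR-297, miR-466, miR-467 and miR-669 only miR-466c-5p and miR-466b-3p could be tested by exact name. With wider names 4 members were tested, of which 1 rose and 2 fell. At 1.54 CPM ± 0.244 in mouse and 4.72 CPM ± 1.36 in rat (SD, n = 3 each), miR-466c-5p rose (1.62 ± 0.29, adjusted p = 0.00152), also adjusted over the list alone, and miR-466b-3p (-0.41 ± 0.28) was not called.

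No list of miRNAs of other cell types was called by camera. The tested miR-200 members all lay above 0, while the vascular, leukocyte and muscle lists held differences both ways. Among 6 vascular and mesenchymal miRNAs, miR-143-3p (0.92 ± 0.28, adjusted p = 0.0247; 0.50 without r1) and miR-222-3p (0.61 ± 0.15, adjusted p = 0.00776) rose, miR-199a-3p fell, and the endothelial miR-126a-3p (-0.13 ± 0.15) and miR-221-3p (-0.01 ± 0.24) were not called. This list was not called (adjusted p = 0.929; adjusted over the list alone, 2 rose and 1 fell), and its median of -0.06 differs in sign from its mean of 0.00189 and the camera direction, up. Of 4 leukocyte and microglia miRNAs, miR-155-5p fell (-0.64 ± 0.23, adjusted p = 0.0407), and miR-146a-5p (-0.41 ± 0.19), miR-150-5p (0.01 ± 0.14) and miR-223-3p (0.39 ± 0.53) were not called (list adjusted p = 0.746; adjusted over the list alone 0). Of 3 epithelial miR-200 members, miR-200a-3p (1.48 ± 0.27, adjusted p = 0.00206) and miR-200c-3p (0.88 ± 0.29, adjusted p = 0.0307) rose and miR-200b-3p (0.74 ± 0.37) was not called (list adjusted p = 0.301). Adjusted over the list alone 2 rose. Without m1, m3 or r4, 1 member was called higher, and without m4, 3 were. With wider names miR-200c-3p was not called (adjusted p = 0.0723). Levels of these members were at most 44.3 CPM ± 10.4 (SD, n = 3), for miR-200b-3p in rat. Mouse library m4 held more miR-200b-3p (42.5 CPM, against 22.9 and 14.1 in m1 and m3) and miR-200c-3p (11.2 CPM, against 5.73 and 5.57). Of 5 muscle miRNAs, 2 rose: miR-499-5p (1.44 ± 0.16, adjusted p = 8.29e-05) and miR-208a-3p (6.74 ± 0.96, adjusted p = 0.00120), the latter at 0 CPM in mouse and 0.683 in rat. A fall was called for miR-133a-3p (-1.11 ± 0.28, adjusted p = 0.00886), and miR-206-3p (0.56 ± 0.24) and miR-133b-3p (-0.92 ± 0.35) were not called (list adjusted p = 0.746). Adjusted over the list alone, 3 of these rose and 2 fell. Of the red blood cell list only miR-144-3p was tested (-1.03 ± 0.56, not called), and no member of the cornea and lens list had an exact name in both tables. With library totals alone, miR-155-5p and miR-133a-3p were not called, and miR-143-3p and miR-155-5p were not when any 1 mouse library was left out, nor was miR-155-5p without r2 or r4.

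**Figure D3:**
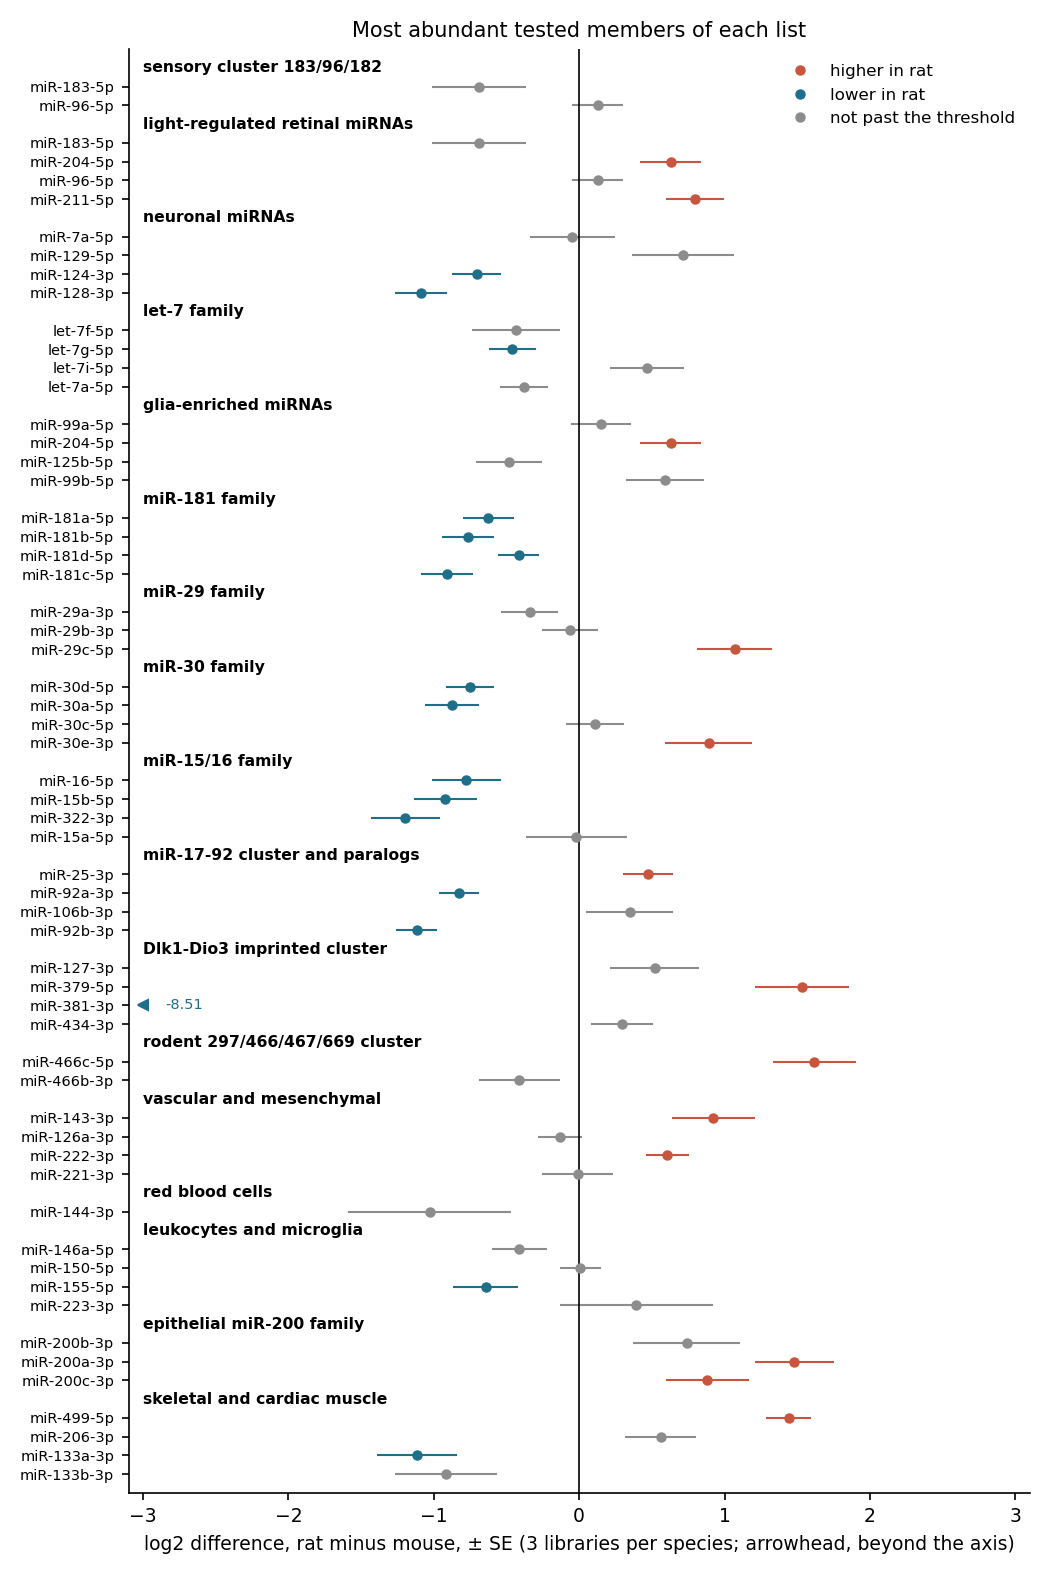
Log2 difference in abundance, rat minus mouse, with its standard error (bars) for up to 4 of the most abundant tested members of each list, from 3 libraries per species. Red members were called higher in rat, blue members lower and grey members were not called; all 4 members of the miR-181 family lie below 0, and miR-381-3p, at -8.51, lies beyond the axis.

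The ratio of the 5p to the 3p arm of a hairpin was compared within libraries, so that scaling between species plays no part. Most hairpins kept their preferred arm: of 169 tested, 162 had the same dominant arm in both species, and the mean log2 ratios had a Spearman rho of 0.973 across hairpins. The arm ratio differed for 41 hairpins by limma (57 at an unadjusted p under 0.05), with 14 shifted to the 5p arm and 27 to the 3p arm in rat. Single libraries moved this number by more than 1.5 times: it was 63 without rat library r1, 27 without mouse library m1 and 26 without mouse library m3.

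The dominant arm differed and the change was called for miR-344b, miR-466c and miR-673. The name miR-344b-5p had 0 counts in mouse and 743 over the 3 rat libraries, at least 232-fold higher in rat against a floor of 3 counts over the group. The name miR-344b-3p had 1434 counts in mouse and 164 in rat. A separate rat name, miR-344b-1-3p, lay at 62.9, 65.4 and 69.9 CPM of all counts in r1, r2 and r4. The rat level of miR-344b-5p was 8.77, 9.65 and 10.2 CPM in the same order. If miR-344b-1-3p were counted with the 3p arm, that arm would lead in rat too. The change of the dominant arm of miR-344b therefore depends on how its 3p reads are named. The 5p share of miR-673, of the Dlk1-Dio3 locus, was 55.4% ± 5.67 in mouse and 22.9% ± 5.37 in rat (SD, n = 3 each; log2 change -2.08 ± 0.31, adjusted p = 0.00528). That of miR-466c was 37.6% ± 8.90 in mouse and 71.4% ± 8.61 in rat (SD, n = 3 each), and was not called without mouse library m3; in mouse its 3p arm had the same counts as those of miR-466b, miR-466e and miR-466p, so these reads are not its own alone.

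The passenger strand miR-185-3p had 884 counts over the 3 mouse libraries and 0 in rat, at least 315-fold lower, beside 46179 and 52458 counts of miR-185-5p. The minor arm of miR-190b fell from 1479 counts in mouse to 7 in rat (log2 change of the ratio 6.20 ± 0.44, adjusted p = 0.000433), and that of miR-186 from 25 to 0. The change of the miR-381 ratio (6.38 ± 0.71, adjusted p = 0.00168) rested on 11 counts of its 5p arm in mouse and 3 in rat; without rat library r4 it was 5.60. Toward the 3p arm, miR-298 went from 98.5% ± 0.987 5p in mouse to 56.1% ± 2.65 in rat (SD, n = 3 each; log2 change -5.80 ± 0.46, adjusted p = 0.000499) and miR-325 from 96.5% ± 0.638 to 85.3% ± 0.988 (SD, n = 3 each; -2.25 ± 0.21, adjusted p = 0.000934). The calls of miR-146a and miR-192 rested on 0 counts of the 3p arm in mouse and on 5 and 13 in rat. Those of miR-192 and miR-542 were lost when any of the 3 mouse libraries or r2 was left out, and that of miR-192 also without r4 and with a pseudocount of 5. Without r1 the change of miR-542 was -1.84, that of miR-192 -2.92 and that of miR-186 5.09. With a pseudocount of 5 the changes were 4.59 for miR-190b, 7.87 for miR-381, 1.75 for miR-186, -0.79 for miR-146a and -0.96 for miR-542.

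**Figure D4:**
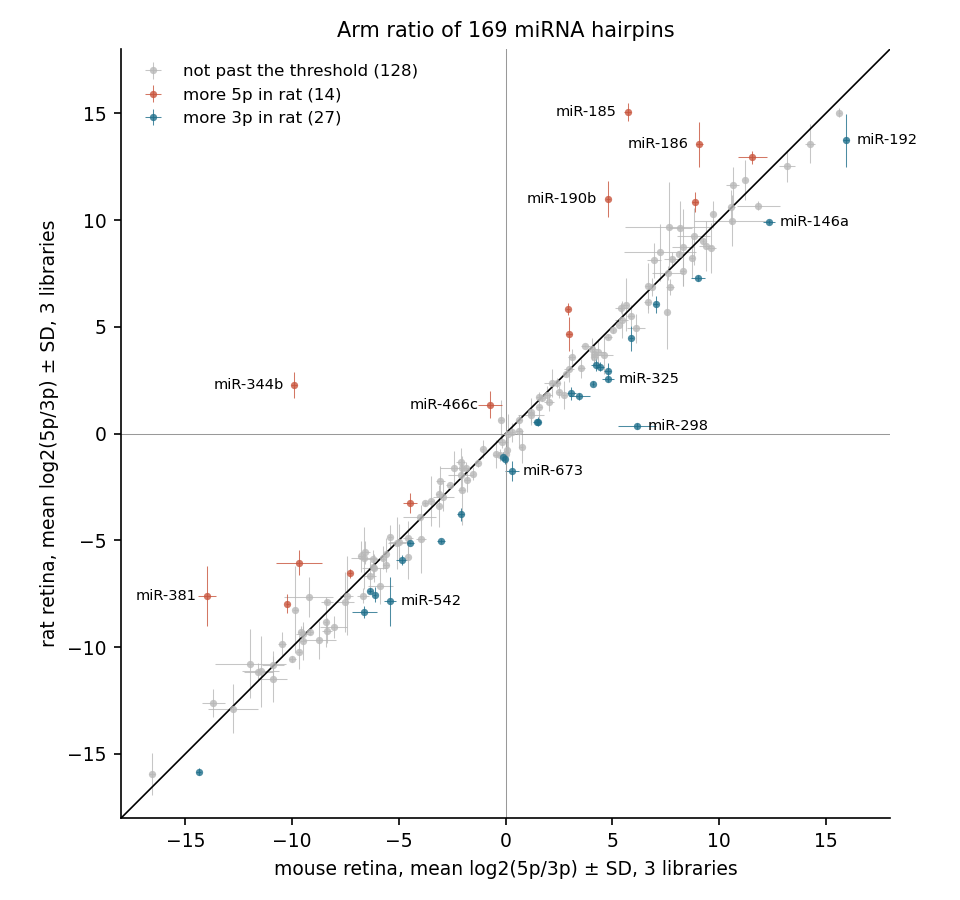
Mean log2 ratio of 5p to 3p counts (0.5 added to each) for 169 hairpins in mouse (x axis) and rat (y axis); bars are the SD over 3 libraries, and the diagonal marks equal ratios. Red hairpins had more 5p in rat (14), blue more 3p (27), and grey were not called; points far from 0 rest on few or 0 counts of the minor arm.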

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

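Names listed for 1 species only held counts that the tests between species did not use. They took 27.5% ± 1.01 (SD, n = 3) of mouse counts and 33.2% ± 2.80 (SD, n = 3) of rat counts. Most of these counts belong to 5 names per species, each with a counterpart under a slightly different name in the other table. In mouse they were miR-182-5p (194025 CPM ± 10372), miR-9-5p (57084 CPM ± 832), miR-191-5p (5745 CPM ± 165), miR-21a-5p (3449 CPM ± 116) and miR-7b-5p (2956 CPM ± 41.7; SD, n = 3 each). In rat they were miR-182 (237210 CPM ± 48133), miR-9a-5p (66314 CPM ± 18579), miR-191a-5p (8361 CPM ± 2887), miR-21-5p (6035 CPM ± 1733) and miR-184 (4083 CPM ± 4589; SD, n = 3 each). Joined under the wider match and scaled there, miR-182 differed by 0.13 ± 0.33 (SE; adjusted p = 0.765) and miR-9-5p by -0.08 ± 0.11 (adjusted p = 0.592), neither called. In the same fit miR-21a-5p was higher in rat (0.51 ± 0.12, adjusted p = 0.00844) and miR-7b-5p lower (-1.29 ± 0.19, adjusted p = 0.00125). No explanation was tested for these names.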

How the results depend on the processing

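The number of differing miRNAs stayed within 1.5 times of the main number with DESeq2, RLE factors (198), upper quartile factors, totals of all names (200), the 10 most abundant left out (196), no filter, a minimum of 50 counts (167), relaxed names (216) and limma-voom (196), and, chosen after the data were seen, wider names (232) and sample weights (267). It also did when any 1 library was left out, with the most calls without r1 (293). With library totals only, 170 were called and 43 were lower, since this scaling moved the median of all tested miRNAs by 0.36. Tested against a fold of 2, 70 were called, 40 higher and 30 lower, which a stricter test must give. No list was called under any alternative except fry, which called 4. The number of differing arm ratios ran from 26 to 63 when 1 library was left out, highest without r1; the cause was not tested. With at least 1 count per library 944 mouse names were detected, as this minimum is lower. Over shared names only, where miR-182 and miR-9 drop out, the 10 most abundant held 70.4% of counts in mouse and 61.6% in rat, and 7 rat miRNAs made up 50%. The Pearson r between species was 0.967 with a pseudocount of 10 CPM, and over filtered miRNAs it was 0.942 with a Spearman rho of 0.916, which leaves out names near 0 in both. No paired analysis was possible because the columns do not carry the replicate numbers of the labels, and animals of 2 species cannot be the same animal. Summing repeated names was not run because no name was repeated.

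Among single miRNAs and lists, the direction turned only for differences that were not called in the main test. The muscle list, which fry called, was among those that turned. With library totals only the log2 differences were 0.18 for miR-7a-5p, 0.061 for miR-29a-3p, 0.33 for miR-29b-3p, 0.43 for miR-15a-5p, 0.20 for miR-126a-3p and 0.41 for miR-221-3p, after the shift of the median. With totals of all names they were 0.0011 for miR-7a-5p, 0.0064 for miR-15a-5p and 0.0099 for miR-221-3p. For miR-150-5p they were -0.094 with upper quartile factors, -0.023 with the 10 most abundant left out, -0.0089 with no filter, -0.044 with relaxed and -0.058 with wider names. For miR-26a-5p they were -0.083 with upper quartile factors, -0.0016 with no filter, -0.037 with relaxed and -0.047 with wider names. For miR-30b-5p they were -0.071 with upper quartile factors, -0.0084 with the 10 most abundant left out, -0.0064 with no filter, -0.040 with relaxed and -0.038 with wider names and -0.014 with limma-voom. With sample weights they were -0.0022 for miR-96-5p, -0.051 for miR-99a-5p, 0.044 for miR-29b-3p, 0.18 for miR-15a-5p, -0.11 for miR-106b-3p, 0.23 for miR-221-3p and -0.29 for miR-148a-3p. The median of the miR-29 list was 0.048 with both arms. The direction of the vascular list turned with both arms (median -0.065) and with fry (median -0.057), and the muscle list's median was -0.80 with wider names, where miR-1a-3p enters and miR-208a-3p drops out. Among lists with under 3 members in the main test, wider names turned the median of the rodent cluster from 0.58 to -2.72. That of the miR-183 cluster went from -0.33 to 0.016. When 1 library was left out, the ranges were -0.50 to 0.15 for miR-7a-5p, -0.25 to 0.31 for miR-15a-5p, -0.010 to 1.10 for miR-223-3p, -0.14 to 0.088 for miR-29b-3p, -0.15 to 0.23 for miR-221-3p and -0.051 to 0.28 for miR-99a-5p. They were -0.13 to 0.56 for miR-106b-3p, -0.35 to 1.12 for miR-148a-3p, -0.00043 to 0.28 for miR-30c-5p, -0.0089 to 0.037 for miR-150-5p, -0.041 to 0.054 for miR-26a-5p, -0.10 to 0.19 for miR-30b-5p and -0.17 to 0.50 for miR-181b-2-3p. List medians ran from -0.086 to 0.091 (vascular), -0.10 to 0.24 (glia), -0.12 to 0.20 (miR-30) and -0.16 to 0.094 (miR-29). With library totals only they were 0.31 (miR-30), 0.24 (miR-29), 0.24 (vascular) and 0.11 (leukocyte), and with both arms the leukocyte median was 0.0068. The cause of these turns was not tested. Of the called list members, miR-204-5p, miR-132-3p, let-7g-5p, miR-181a-5p, miR-181d-5p, miR-30e-3p, miR-16-5p, miR-25-3p, miR-143-3p and miR-155-5p were not called when any 1 mouse library was left out, which leaves fewer samples. Nor were miR-132-3p, let-7g-5p and miR-155-5p without r2 or r4, or miR-181d-5p without r4; miR-132-3p also lost its call with DESeq2, library totals only, RLE factors, totals of all names and a minimum of 50 counts, miR-133a-3p was not called without m1, and miR-200c-3p lost its call under 8 alternatives beside the fold test. Depth limits only rare names: 10 counts are under 1 CPM in every library.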

Other observations

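In this part the wider name match and the tests of depth, of other eye tissue and of the 16-fold differences were chosen after the results were seen; those of base composition, neighbouring genes, the X chromosome and other splits were chosen before. Under the wider match, several miRNAs absent from the main test differed between the retinas (edgeR, adjusted p). The muscle miRNA miR-1a-3p (miR-1 in rat) was at 825 CPM ± 147 in mouse and 25.4 CPM ± 19.8 in rat (SD, n = 3 each), a log2 difference of -5.03 ± 0.58 (SE, adjusted p = 0.000361). Its rat level leaned on r1, at 48.0 CPM against 16.9 in r2 and 11.2 in r4. The rat table also lists miR-1b, at 306 CPM ± 41.4 of all counts (SD, n = 3), where miR-1b-3p had 0.311 CPM ± 0.0571 in mouse, so that a split of the reads between names stays open for this fall. Of the other muscle miRNAs in the same fit, miR-133a-3p (-1.16 ± 0.27, adjusted p = 0.00870) and miR-133b-3p (-0.97 ± 0.31, adjusted p = 0.0337) also fell, both under 5 CPM, while miR-499-5p rose (1.38 ± 0.15, adjusted p = 0.000216) and miR-206-3p (0.49 ± 0.22) was not called. The neuronal miR-218-5p rose (1.46 ± 0.19, adjusted p = 0.000616), as did miR-504-5p (2.21 ± 0.28, 0.000537), miR-28a-3p (2.13 ± 0.27, 0.000576) and miR-341-3p of the Dlk1-Dio3 locus (1.60 ± 0.12, 3.41e-05), and miR-344-3p fell (-2.75 ± 0.12, 3.66e-06). Of the red blood cell miRNAs, miR-486a-5p was higher (1.03 ± 0.11, adjusted p = 0.000214) and miR-451a lower (-2.77 ± 0.38, adjusted p = 0.00085). The mouse name miR-486b-5p, with a similar count, was not joined to the rat name miR-486. A split of the mouse reads between these names therefore stays open for the rise of miR-486a-5p. Of the cornea and lens list, miR-203-3p fell (-1.03 ± 0.12, adjusted p = 0.000422), and miR-184-3p (2.33 ± 1.03) and miR-205-5p (0.65 ± 0.60) were not called. Of the miR-200 list, miR-429-3p (1.56 ± 0.44, adjusted p = 0.0207) and miR-200a-3p (1.40 ± 0.28, adjusted p = 0.00442) rose, and miR-200b-3p and miR-200c-3p were not called. The level of miR-429-3p was 0.388 CPM in mouse and 1.12 in rat. In the rodent cluster miR-466d-3p (-6.86 ± 0.40, adjusted p = 1.09e-05) and miR-297a-3p (-8.98 ± 0.59, adjusted p = 0.000147) fell. They were at 3.16 and 2.27 CPM in mouse and 0.0195 and 0 in rat. Their rat names, miR-466d and miR-297, carry no arm and were joined to the arm with more counts in mouse. In mouse, miR-297a-3p had the same counts as miR-297b-3p and miR-297c-3p. A difference in naming therefore stays open for both falls.

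Log2 deviations of r1 from the mean of r2 and r4 were centred on their median over 367 miRNAs with at least 50 counts in each rat library. That median was -0.704 before centring, and the difference between r2 and r4 was centred likewise. Rat library r1 differed from r2 and r4 by a median absolute log2 deviation of 0.522 over the 77 miRNAs with at least 10000 counts in each rat library, where r2 and r4 differed by 0.123. This argues against its lower depth as the cause, since r2 lay closer to r1 than to r4 in depth and yet deviated less from r4. Tissue from other parts of the eye could not be decided, as the cornea and lens miRNAs moved apart in r1. After centring, miR-184 deviated by 3.44 (9369 CPM of all counts, against 1761 and 1119 in r2 and r4). The centred deviation of miR-203a-3p was 0 (52.0 CPM, against 78.4 and 91.7), and that of miR-205 was -0.879. The profile of such tissue was not measured. A bias by base composition could not be decided: the Spearman rho across 300 miRNAs between the deviation and hairpin GC was 0.174, against 0.00339 for r2 and r4, and no biological explanation was tested.

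The 20 miRNAs called with a difference over 16-fold include 11 hairpins with the other arm tested, each counted once. The other arm differed the same way by a median of 2.34 (log2) and by over 1 in 7 of 11, so a difference in the amount of the whole precursor may underlie part of these, as a hypothesis. Some of these other arms lay near the floor, such as miR-505-5p at 0.356 CPM in mouse and 1.85 in rat. Counting or annotation of the single mature name stays open, as the lower quartile was -0.0312: the other arm did not follow for miR-185-3p (0.13, adjusted p = 0.517) or miR-29b-1-5p (-0.06, adjusted p = 0.806), and went the other way for miR-344b-5p (-3.23) and miR-181a-2-3p (-0.63). The partners of miR-29b-1-5p and miR-181a-2-3p carry a name that other copies of the hairpin share, and the 5p arm of miR-381 had too few counts to be tested. For miR-344b-5p the partner left out the rat name miR-344b-1-3p, so its fall may reflect naming.

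MiRNA genes lying within 10 kb of each other in the mouse genome (GRCm38.p6) tended to differ together between the species. Over 30 such clusters the mean within-cluster SD of the log2 difference was 1.12, against 1.48 for permuted differences (one-sided permutation p = 0.021; 0.00086 without the 3 clusters of the Dlk1-Dio3 locus, and 0.00042 on ranks), which argues against neighbours being no more alike than random pairs. The result leaned on a few clusters: p was 0.064 without miR-20b and miR-363 (4.97 and 7.59) and 0.051 without miR-296 and miR-298 (-4.24 and -3.12), and between 0.0018 and 0.033 without any other. Dosage of the X chromosome could not be decided: the median of 31 X-linked genes exceeded that of 194 autosomal genes by 0.056 (permutation p = 0.64), but with 16 above and 15 below 0, from -3.24 to 7.59, a median within 0.3 was too weak a bound to exclude it. A hypothesis left open is that transcription of shared primary transcripts differs between the species, which the permutation p of 0.021 is in line with, while annotation that differs by locus was not tested.

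The 6 libraries can be split into groups of 3 in 10 ways, too few for a share under 0.05. Each other split also mixes the species in both groups, which widens the spread within groups. Low numbers in those splits therefore say little about chance. The number of differing miRNAs in the species split was 102 higher and 97 lower, in 1 of 10 splits, and the highest of the other splits was 0. For arm ratios it was 41, against at most 1. For lists it was 0, which 10 of 10 splits reached, with 2 the highest of the others.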
